A study of Homo sapiens with 9 samples.

How the data were processed

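The authors' deposited table of raw read counts per gene was used as given, with 61533 rows, each an Ensembl gene identifier with its version and a gene name, and 9 columns, one per library. Per the labels, RNA was extracted with a column kit and libraries were made with the NEBNext Ultra II RNA kit. The labels give the extracted molecule as genomic DNA, while the protocol and the counts are those of RNA, so the libraries were treated as RNA. The labels name FastQC, cutadapt, STAR and the human genome build hg38, without versions. The tool that counted the reads, the gene annotation release, whether counting used the strand, the dose and time of each treatment, and whether the replicates came from separate donors or cultures are not given in the sources used here.

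The values were whole numbers, and the column totals ran from 1332714 to 31791652 and differed between libraries, as those of raw counts do. Each column was matched to its library by the group and replicate number in its name, with 0 value columns left unmatched. The column names put the letter D before the number where the titles have rep, and the letter is not explained. No pair of libraries in a group was near-identical: the chi-square per gene between libraries of one group ran from 19.83 to 252.7. Of the gene identifiers, 58356 were found in GENCODE release 29, which gave the GRCh38 positions. Gene symbols shared by more than 1 row numbered 123, and each row was kept as its own gene. Exon overlaps were looked up in the same release for the 129 protein-coding genes named in the comparisons. Of these, 14 share exon bases with another protein-coding gene and 7 share at least 10% of their own exon bases, so the counts of those 7 depend on how shared reads were assigned.

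Genes were kept with the filterByExpr function of edgeR (minimum count 10), which left 15045 genes that held between 99.85% and 99.91% of the counts of each library. Counts were scaled with edgeR's trimmed mean of M-values (TMM), with factors from 0.8972 to 1.134, and expression is given as counts per 1e6 counts (CPM) after that scaling. Each of the 3 comparisons was tested with the edgeR quasi-likelihood F test, two-sided, in a joint fit of the 9 libraries. Benjamini-Hochberg adjusted p-values under 0.05 were called. The unpaired fit had the group alone as a term and 6 residual degrees of freedom. The paired fit added the replicate number as a block and had 4. Standard errors (SE) of log2 fold changes were taken from the F statistic. The p-values measure only the spread between these libraries, since nothing in the labels says that replicates are separate donors or cultures.

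Whether equal replicate numbers belong together was checked on log2 CPM (prior count of 2) after subtraction of each group's mean. Libraries with the same number in different groups had correlations of these deviations from 0.462 to 0.832. Libraries with different numbers had correlations from -0.582 to -0.00459. Subtracting the mean makes deviations cancel within a group, so positive values for equal numbers force negative ones on balance for different numbers. Each of the 9 libraries was closest to its own number in both other groups. The common dispersion was 0.325 in the unpaired fit and 0.0481 in the paired fit. The numbers therefore followed a difference shared across groups, of a kind the labels do not name, and both fits are reported. The first 3 principal components held 43%, 27.1% and 14.4% of the variance.

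The test was tried on simulated counts with the dispersions, totals and replicate differences of these libraries, for the comparison of PKS3053 plus IL-33 with IL-33 and 14689 genes, of which 100 were changed at each size. At a true log2 change of 1, the unpaired fit recovered 0% and the paired fit 59%. At a true log2 change of 2, they recovered 30% and 98%. The unpaired fit called 0 unchanged genes and the paired fit 11. With every 26S proteasome gene moved by a log2 change of 0.5 in the simulation, the list test described next called that list and no other in both fits at its preset correlation. With an estimated correlation its adjusted p was 0.0552 in the unpaired and 0.0133 in the paired fit. The simulated genes were drawn independently of each other. The simulation therefore does not show how the preset correlation behaves where genes of a list vary together.

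Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, on log2 CPM with a prior count of 2, for lists with at least 5 tested members and with adjustment over the lists of one comparison. The same lists were tested with the correlation estimated from the data and with fry, which asks whether a list's genes moved on balance in one direction and does not compare them with other genes. The 31 lists held 635 genes, of which 603 were tested. They were type 2 effector genes, other cytokines and chemokines, ILC2 identity, NF-κB targets, PPARγ and PPAR targets, fatty acid oxidation, fatty acid synthesis and triglyceride storage, cholesterol biosynthesis, the immunoproteasome with antigen processing, and the constitutive 26S proteasome. Further programmes were the heat shock response, the integrated stress response, the unfolded protein response of the endoplasmic reticulum, NRF2 targets, p53 targets, cell cycle, MYC with ribosome biogenesis, glycolysis with hypoxia, and nuclear-encoded oxidative phosphorylation. Interferon-stimulated genes, co-stimulation and checkpoint receptors, ribosomal proteins and immediate early genes completed the programmes. The lists of other cell types were markers of T cells, NK cells with ILC1, ILC3, B cells, monocytes with macrophages and dendritic cells, mast cells with basophils and eosinophils, fibroblasts with stroma, and red cells with platelets.

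The genes named in the comparisons were chosen by a rule. It took the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, which chance gives to 10% of genes at 3 against 3. It added 18 genes named for the question (FABP4 among them, which did not pass the filter), the 4 genes with the smallest adjusted p in each list, called members against the direction of their list, and genes called in both the IL-33 and the PKS3053 comparison. Some results the rule selects are withheld and not reported here. The groups, tests, unpaired fit as the primary one, gene lists, naming rule and most alternative settings were fixed before the data were examined. The paired fit's own alternatives, the thinning of all libraries to the shallowest one and the exon lookup were chosen after the data were seen.

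The relation between the IL-33 response and the PKS3053 response was measured across genes as a correlation and a covariance of log2 fold changes. The IL-33 libraries enter both with opposite sign, so the values are set beside 20 simulations of counts without any effect. Limits for a count of 0 were taken as 3 counts of the library's total and cover counting error only. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.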

Results

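RNA sequencing measured transcript levels in 9 libraries of human group 2 innate lymphoid cells (ILC2), innate lymphocytes that make type 2 cytokines. The cells were left unstimulated, given IL-33 (an alarmin cytokine that acts through the receptor ST2), or given IL-33 together with PKS3053, with 3 libraries in each group. The series' design text describes PKS3053 as an antagonist of PPARγ, a lipid-sensing nuclear receptor, and the series title also names the immunoproteasome. Total counts, in M (1e6 counts), were 23.58, 14.43 and 28.04 in the unstimulated libraries of replicates 1, 2 and 3. They were 21.65, 20.14 and 21.09 with IL-33, and 18.15, 1.333 and 31.79 with PKS3053 plus IL-33. The PKS3053 plus IL-33 library of replicate 2 was thus shallow: 13323 genes had a count in it, against 21271 to 23495 in the other libraries. A count of 0 allowed up to 2.25 CPM there and up to 0.0944 to 0.208 CPM elsewhere, as far as counting error goes. Mitochondrial transcripts took 0.747% to 1.20% of the counts and the 10 most abundant genes 7.49% to 9.88%. CPM values are means ± SD of 3 libraries and log2 fold changes carry their SE. Calls came from 2 fits, an unpaired one with the group alone and a paired one with the replicate number as a block.

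To find the transcripts that IL-33 changed in ILC2, the IL-33 libraries were compared with the unstimulated ones. In the paired fit IL-33 raised the type 2 cytokine genes IL5 and IL13, the growth factor gene CSF2 and the chemokine gene CCL1. IL5 (ENSG00000113525.10, chromosome 5, 132541444 to 132556838, GRCh38) went from 502 ± 178 to 4253 ± 2052 CPM (n = 3), a log2 change of 2.87 ± 0.43 with an adjusted p = 0.0131. IL13 (ENSG00000169194.10, chromosome 5, 132656263 to 132661110) went from 302 ± 226 to 2106 ± 1207 CPM, a log2 change of 2.77 ± 0.47 with an adjusted p = 0.0306. CSF2 (ENSG00000164400.6, chromosome 5, 132073790 to 132076170) rose by 2.14 ± 0.26 from 34.7 ± 17.2 CPM (adjusted p = 0.00391), and CCL1 rose by 2.37 ± 0.43 from 247 ± 183 CPM (adjusted p = 0.039). IL1RL1 (ENSG00000115602.17, chromosome 2, 102311502 to 102352037), which encodes ST2, rose from 61.8 ± 25.6 to 213 ± 56.6 CPM, a log2 change of 1.84 ± 0.24 with an adjusted p = 0.00654. Each of these 5 genes was higher with IL-33 in 3 of 3 replicate pairs, and none was called in the unpaired fit, where each had an adjusted p = 1.00. IL13 and CCL1 lost their paired calls without the unstimulated library of replicate 2 or of replicate 3, and CCL1 also without the IL-33 library of replicate 2 or of replicate 3. IL5, CSF2 and IL1RL1 kept theirs without any 1 of the 6 libraries.

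Among the other genes of ILC2 identity, the co-stimulatory receptor gene ICOS rose 3.06-fold, the chemokine receptor gene CCR4 2.72-fold and TNFRSF25 2.55-fold in the paired fit (adjusted p = 0.00257, 0.0148 and 0.0387). IL7R, the receptor gene for IL-7, went the other way, from 202 ± 58.0 to 87.6 ± 8.56 CPM, a log2 change of -1.19 ± 0.23 (adjusted p = 0.0492). Of the 24 tested genes of this list, 5 rose and 1 fell over all genes, while 6 rose and 7 fell when adjusted over the list alone. The largest rises included the chemokine gene CXCL10 (9.8-fold), the cytokine gene IL22 (7.45-fold), the lipid transporter gene MFSD2A (6.92-fold) and the chaperone gene DNAJC5B (log2 change 3.32 ± 0.45). FEZ1 rose 6.13-fold, TMPRSS6 6.11-fold and ACE 5.75-fold, with 37.3% of the exon bases of ACE lying in a readthrough gene as well. The genes that fell without overlap between groups were PLCD1, GPR155, IL7R and MBOAT2, with log2 changes of -1.53 ± 0.3, -1.37 ± 0.27, -1.19 and -1.04 ± 0.19. Without the unstimulated library of replicate 2 or of replicate 3, CCR4, TNFRSF25, IL7R, ACE, PLCD1, GPR155 and MBOAT2 lost their calls, and CXCL10 and TMPRSS6 lost theirs without that of replicate 3. ACE, PLCD1 and GPR155 also lost their calls with DESeq2 size factors or with total counts in place of TMM, and IL7R with the size factors. GATA3, the lineage transcription factor gene, stood at 660 ± 152 CPM without and 742 ± 161 CPM with IL-33 and was not called (adjusted p = 0.831).

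Targets of NF-κB, the transcription factor downstream of ST2, rose as a set. Their median log2 change was 0.78 in the unpaired fit with a camera adjusted p = 3.72e-19 (adjusted p = 0.0068 with an estimated correlation). Of the 29 tested members, 24 were higher in all 3 pairs. Random signs in each pair would give that to 12.5% of genes, which is not the share among all tested genes, and members of a list can move together. In the paired fit the adjusted p = 3.85e-18, and the adjusted p = 0.315 with an estimated correlation. In that fit 6 of the 29 members rose over all genes and 24 rose when adjusted over the list alone. NFKBIZ (ENSG00000144802.11, chromosome 3, 101827991 to 101861022) rose from 61.9 ± 5.81 to 485 ± 359 CPM, a log2 change of 2.68 ± 0.29 (adjusted p = 0.00257). NFKBIA rose by 1.36 ± 0.19 from 533 ± 154 CPM, REL by 1.47 ± 0.2 and CD83 by 1.39 ± 0.26. REL and CD83 lost their calls without the unstimulated library of replicate 3 or without the IL-33 library of replicate 2. CD83 also lost its call without the unstimulated library of replicate 2 or the IL-33 library of replicate 3. With DESeq2 size factors or with total counts in place of TMM, CD83 was not called either. The median log2 changes of the 26S proteasome list in the pairs of replicates 1, 2 and 3 were 0.05, 0.43 and 0.47, beside 0.57, 1.18 and 0.90 for the NF-κB targets.

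Camera called 12 further lists upward in the unpaired fit. Type 2 effector genes had a median log2 change of 1.15 (adjusted p = 5.49e-07), other cytokines and chemokines 0.82 (adjusted p = 1.01e-07) and integrated stress response genes 0.42 (adjusted p = 4.14e-05). Each had an adjusted p = 0.167 with an estimated correlation. MYC and ribosome biogenesis genes had a median of 0.69 (adjusted p = 1.91e-11, and adjusted p = 0.266 with an estimated correlation), and heat shock genes 0.46 (adjusted p = 6.04e-07, and adjusted p = 0.198 with an estimated correlation). The constitutive 26S proteasome (0.31, adjusted p = 5.26e-10), the immunoproteasome list (0.35, adjusted p = 0.00409) and co-stimulation receptors (0.49, adjusted p = 0.00409) each had an adjusted p = 0.265 with an estimated correlation. Interferon-stimulated genes (0.63, adjusted p = 8.46e-05), cholesterol biosynthesis (0.17, adjusted p = 0.0121) and glycolysis (0.16, adjusted p = 0.0427) had an adjusted p = 0.677 with an estimated correlation, and oxidative phosphorylation (0.11, adjusted p = 0.0121) had 0.857. Members that rose in the paired fit were NOLC1, NOP56, IFIT1, IFIT3, CD274, CTLA4, TNFRSF9, HSP90AB1, SLC3A2, WARS1, CXCL8 and the immediate early gene DUSP2. Their folds ran from 1.78 for SLC3A2 to 3.1 for CXCL8. None of these 12 genes stayed called without the unstimulated library of replicate 3. CXCL8, NOP56, CD274, CTLA4, TNFRSF9, HSP90AB1, SLC3A2 and WARS1 also lost their calls with DESeq2 size factors or with total counts in place of TMM. MYC itself missed the threshold at 2.52-fold (adjusted p = 0.0691).

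The block changed the call of 2 lists. NRF2 targets had a median of 0.18 in both fits, with an adjusted p = 0.0908 in the unpaired and 0.0496 in the paired fit (adjusted p = 0.379 with an estimated correlation in the latter). T cell markers were lower as a set in the paired fit, with a median of -0.35 and an adjusted p = 0.000351 (adjusted p = 0.198 in the unpaired fit, and adjusted p = 0.315 with an estimated correlation in the paired fit). None of their 15 tested members was called. LCK stood at 1026 ± 366 CPM without and 724 ± 324 CPM with IL-33, and CD3E at 102 ± 116 and 75.6 ± 82.9 CPM, both lower in 3 of 3 pairs. In the unstimulated library of replicate 2, LCK stood at 786 CPM of the library total and CD3G at 0.347, so LCK does not follow T cells alone. MS4A2, a mast cell and basophil marker, fell 3.07-fold from 19.4 ± 9.47 CPM in the paired fit (adjusted p = 0.0194), and lost its call without the unstimulated library of replicate 2 or of replicate 3. With an estimated correlation, camera called 1 of the 13 lists of the unpaired fit, the NF-κB targets, and 0 of the 15 of the paired fit, and fry called the same list alone in the unpaired fit and 0 in the paired one. The other 16 lists had camera adjusted p-values between 0.201 for the unfolded protein response and 0.889 for NK cell markers in the unpaired fit.

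For the genes the series is about, PPARG stood at 151 ± 62.3 CPM without and 249 ± 55.9 CPM with IL-33 and missed the threshold (0.76 ± 0.2, adjusted p = 0.143 in the paired fit). The list of PPAR targets had a median log2 change of -0.05 and a camera adjusted p = 0.805, and 1 member, ABCG1, fell 2.96-fold in the paired fit (adjusted p = 0.0278), a call lost without the unstimulated library of replicate 2 or of replicate 3. The immunoproteasome subunit genes PSMB8, PSMB9 and PSMB10 had log2 changes of 0.32 ± 0.15, 0.25 ± 0.15 and 0.44 ± 0.17, and the constitutive subunit gene PSMB5 0.47 ± 0.19, with adjusted p-values from 0.346 for PSMB10 to 0.62 for PSMB9. IL4 (1.19 ± 0.29), IL9 (1.28 ± 0.9), FABP5 (0.63 ± 0.22), PLIN2 (0.13 ± 0.15), CPT1A (-0.22 ± 0.2) and CD36 (0.48 ± 0.36) were not called either, with adjusted p-values from 0.109 for IL4 to 0.818 for PLIN2. AREG stood at 0.507 ± 0.0995 CPM unstimulated and 0.599 ± 0.351 CPM with IL-33, with a change of 0.07 ± 0.68.

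Over all 15045 genes, edgeR called 0 in the unpaired fit, with a smallest adjusted p of 1 and 347 genes at an unadjusted p under 0.05, where chance gives 752. DESeq2 called 17 genes and limma voom 0 in that design. The paired fit called 79 genes higher and 8 lower, with 1650 at an unadjusted p under 0.05. That count of 87 was 265, 28 and 23 without the unstimulated library of replicate 1, 2 or 3, and 182, 23 and 37 without the IL-33 library of replicate 1, 2 or 3. It was 896, 0 and 44 without all libraries of replicate 1, 2 or 3. Of the 39 genes called among those named, 38, 15 and 11 stayed called without the unstimulated library of replicate 1, 2 or 3, and 35, 13 and 21 without the IL-33 library of replicate 1, 2 or 3.

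**Figure D1:**
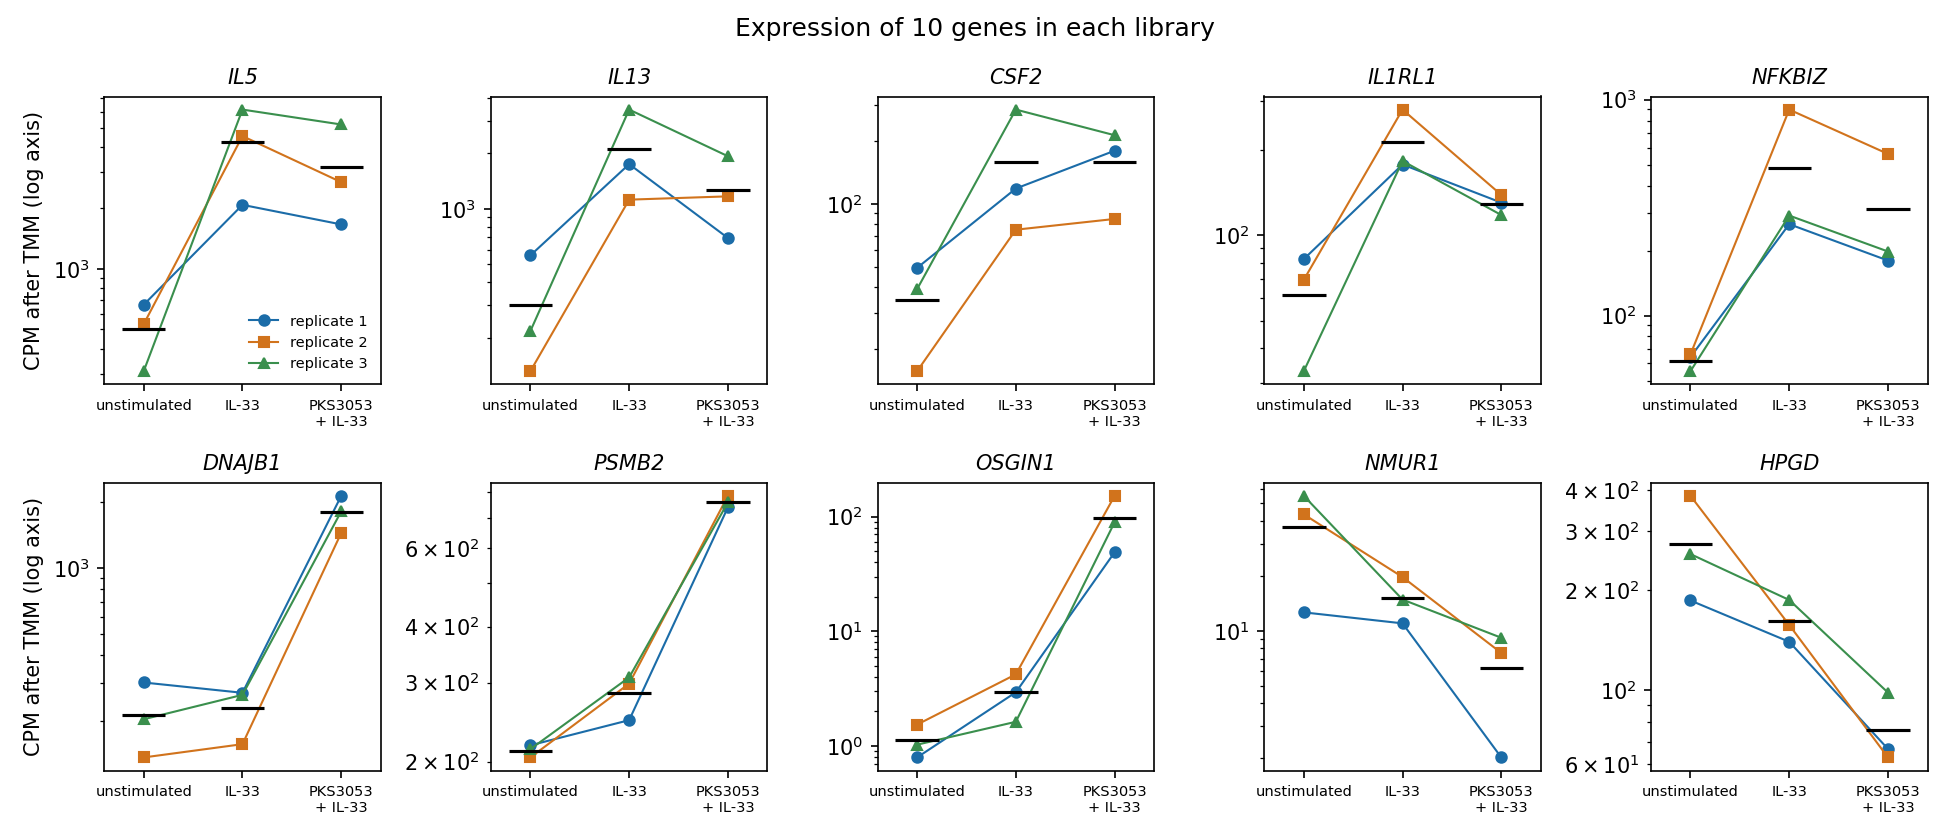
Expression of 10 genes in each library, in CPM after TMM scaling on a log axis, with lines joining libraries of one replicate number and black bars at the group means. IL5 averages 502, 4253 and 3176 CPM in unstimulated, IL-33 and PKS3053 plus IL-33 libraries, and DNAJB1 averages 214, 230 and 1801 CPM.

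To find what PKS3053 changed in the presence of IL-33, the libraries with both were compared with those of IL-33 alone. PKS3053 raised genes of protein folding, of the response to oxidants and of the proteasome, the complex that degrades proteins tagged with ubiquitin. The co-chaperone gene DNAJB1 (ENSG00000132002.9, chromosome 19, 14514770 to 14529770) rose from 230 ± 63.4 to 1801 ± 345 CPM (n = 3), a log2 change of 2.97 ± 0.36 in the unpaired fit with an adjusted p = 0.0289. BAG3 (ENSG00000151929.10, chromosome 10, 119651370 to 119677819), a co-chaperone of HSP70, rose from 0.852 ± 0.469 to 34.9 ± 15.7 CPM, a log2 change of 5.33 ± 0.67 (adjusted p = 0.0289). OSGIN1 (ENSG00000140961.14, chromosome 16, 83948282 to 83966332), an NRF2 target, rose from 2.92 ± 1.29 to 96.8 ± 52.0 CPM, a log2 change of 5.04 ± 0.56 (adjusted p = 0.0289). PSMB2 (ENSG00000126067.12, chromosome 1, 35599544 to 35641844), a subunit gene of the proteasome core, rose from 285 ± 32.7 to 760 ± 22.5 CPM, a log2 change of 1.42 ± 0.17 (adjusted p = 0.0289). ZFAND2A had the smallest adjusted p, 0.00259, with a log2 change of 2.79 ± 0.19. Each of these 5 genes was higher in 3 of 3 pairs.

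The other large rises in the unpaired fit were MLLT11 (8.28-fold), BRF2 (6.72-fold), NAP1L2 (5.1-fold), ABHD4 (5.04-fold), HSPH1 (4.5-fold) and CYB5R1 (4.46-fold). NAP1L2 and ABHD4 lost their unpaired calls with total counts in place of TMM, and ABHD4 with DESeq2 size factors too. Of the exon bases of BRF2, 59.6% also lie in ADGRA2 on the opposite strand, and 11.6% of those of MLLT11 lie in CDC42SE1. UCHL1 (9.6-fold), FAM241B (8.61-fold), HSPA6 (7.36-fold) and B4GALNT1 (7.18-fold) rose in the paired fit, while their unpaired adjusted p-values ran from 0.081 for FAM241B to 0.162 for B4GALNT1. The largest falls, called in the paired fit alone, were NAB2 (-1.83 ± 0.29), MFSD3 (-1.64 ± 0.35), TP73 (-1.58 ± 0.31), NMUR1 (-1.52 ± 0.34), NAA80 (-1.45 ± 0.34), BCOR (-1.3 ± 0.2) and EEF2K (-1.29 ± 0.28). Then came EDARADD (-1.28 ± 0.24), PDE4A (-1.19 ± 0.2) and ODAPH (-1.18 ± 0.27), and 12.8% of the exon bases of NAA80 lie in HYAL3. Unpaired adjusted p-values of these 10 genes ran from 0.286 for BCOR to 0.99 for EEF2K. Of these 10, only NAB2 and BCOR stayed called in the paired fit without the shallow library, where the falls over all genes went from 82 to 9, and B4GALNT1 lost its call as well.

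The 34 constitutive 26S proteasome genes had a median log2 change of 1.29 in the unpaired fit, with a camera adjusted p = 2.45e-52 (adjusted p = 0.0245 with an estimated correlation). Of them, 33 were higher in all 3 pairs, and the list's median was 1.23, 1.37 and 1.17 in the pairs of replicates 1, 2 and 3. Over all genes 4 members rose in the unpaired fit, namely PSMB2, PSMC6, PSMD13 and VCP, and 29 in the paired fit. With total counts in place of TMM, PSMC6 and PSMD13 lost their unpaired calls. Adjusted over the list alone, 33 rose in either fit. PSMB7 rose 3.01-fold and PSMD11 3.04-fold in the paired fit, and 10.4% of the exon bases of PSMD13 lie in SIRT3 on the opposite strand. PSMB5 (ENSG00000100804.19, chromosome 14, 23016543 to 23035230) went from 196 ± 40.3 to 494 ± 80.2 CPM, with an adjusted p = 0.326 in the unpaired and 0.00243 in the paired fit. The immunoproteasome counterparts were not called: PSMB8 (ENSG00000204264.12, chromosome 6, 32840717 to 32844703) stood at 353 ± 112 and 314 ± 65.5 CPM, a log2 change of -0.17 ± 0.27 (adjusted p = 1.00). PSMB9 changed by -0.09 ± 0.21 and PSMB10 by -0.02 ± 0.19, with 30.7% of the exon bases of PSMB10 lying in a readthrough gene. The immunoproteasome and antigen processing list had a median of -0.03 and an adjusted p = 0.595, and its 1 called member was the assembly factor gene POMP, at 1.94-fold in the paired fit (adjusted p = 0.0267, and 0.686 unpaired), which was not called without the shallow library.

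Heat shock genes had a median log2 change of 1.52 (camera adjusted p = 6.16e-41, and adjusted p = 0.00581 with an estimated correlation), and 21 of 22 were higher in all 3 pairs. Over all genes 4 rose in the unpaired fit and 21 in the paired fit, and 21 rose in either when adjusted over the list alone. HSP90AA1 went from 507 ± 99.4 to 1905 ± 648 CPM, called in the paired fit (adjusted p = 2.63e-04, and 0.0853 unpaired). NRF2 targets had a median of 1.34 (adjusted p = 1.03e-18, and adjusted p = 0.00187 with an estimated correlation). Of the 20 tested, 2 rose in the unpaired fit, OSGIN1 and TALDO1, and 11 in the paired fit, PIR and the ferritin gene FTL among them. Adjusted over the list alone 11 and 15 rose. TALDO1 lost its unpaired call with total counts in place of TMM. Integrated stress response genes had a median of 0.31 (adjusted p = 1.05e-06, and adjusted p = 0.0442 with an estimated correlation), with 0 members called in the unpaired fit and 7 of 23 in the paired fit. These included ATF3 (2.37-fold), ATF4 (1.63-fold), DDIT3 (2.46-fold), SLC7A11 (3.58-fold) and PPP1R15A (1.86-fold). The unfolded protein response list had a median of 0.29 (adjusted p = 0.000107, and adjusted p = 0.121 with an estimated correlation), and HSPA5 was its 1 called member, at 1.88-fold in the paired fit, and lost its call without the shallow library. In the paired fit the estimated correlation gave an adjusted p = 0.141 for the proteasome, 0.0944 for heat shock, 0.0844 for NRF2 targets and 0.210 for the integrated stress response. Without the shallow library, 24 of 34 proteasome, 17 of 22 heat shock, 9 of 20 NRF2 and 1 of 23 integrated stress response genes were called higher in the paired fit, with medians of 1.19 and 1.46 for the first 2 lists. Without it in the unpaired fit 0 members of these lists were called over all genes, and 33, 21 and 12 of the first 3 lists when adjusted over the list alone.

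NF-κB targets were lower with PKS3053 than with IL-33 alone, with a median log2 change of -0.50 and a camera adjusted p = 0.00087 (adjusted p = 0.118 with an estimated correlation), and 20 of 29 were lower in all 3 pairs. In the paired fit 2 members fell, TNFRSF4 (-1.9 ± 0.31, adjusted p = 0.00612, and 1.00 unpaired) and REL (-0.92 ± 0.21, adjusted p = 0.0405, and 0.408 unpaired). Without the shallow library neither was called. NFKBIA was not called (-0.56 ± 0.18, adjusted p = 0.156). Cell cycle genes had a median of -0.34 (adjusted p = 0.0182, and adjusted p = 0.926 with an estimated correlation), with 0 of 34 members called in either fit. Among ILC2 identity genes the paired fit called HPGD (-1.06 ± 0.22), CCR4 (-1.0 ± 0.22) and NMUR1 lower and IL7R (1.0 ± 0.23) higher, of 24 tested. The type 2 effector gene TNFSF11 (-1.11 ± 0.23), the immediate early genes IER2 (-0.88 ± 0.16) and DUSP2 (-1.31 ± 0.27) and the glycolysis regulator gene PFKFB3 (-0.94 ± 0.21) fell in the paired fit. Unpaired adjusted p-values of these 8 genes ran from 0.446 for HPGD to 1 for CCR4, and in the paired fit none of them stayed called without the shallow library.

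Oxidative phosphorylation genes (median 0.18, adjusted p = 0.00381) and ribosomal proteins (0.16, adjusted p = 0.00598) rose as sets, each with an adjusted p = 0.926 with an estimated correlation. NDUFA4 (1.71-fold) was the 1 called member of the former, and ALDOA (2.32-fold, with 68.0% of its exon bases also in a readthrough gene) rose in the glycolysis list, both in the paired fit and neither without the shallow library. Camera called none of the remaining lists in either fit. Adjusted p-values in the unpaired fit were 0.235 for ILC2 identity and for monocyte markers, 0.287 for other cytokines, MYC with ribosome biogenesis, glycolysis and interferon-stimulated genes, and 0.373 for co-stimulation receptors. They were 0.421 for fatty acid synthesis and for mast cell markers, 0.429 for type 2 effector genes and for B cell markers, 0.665 for cholesterol biosynthesis and 0.702 for p53 targets. PPAR targets, fatty acid oxidation, T cell markers and fibroblast markers had 0.749, red cell and platelet markers 0.783, NK cell markers 0.825, immediate early genes 0.857 and ILC3 markers 0.942. The median and the direction given by camera differed in sign for fatty acid oxidation, the immunoproteasome list, immediate early genes and ILC3 markers.

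IL5 stood at 4253 ± 2052 CPM with IL-33 and 3176 ± 1814 CPM with PKS3053 added, a log2 change of -0.44 ± 0.39 that was not called (adjusted p = 0.626, paired). IL13 (-0.61 ± 0.44), IL4 (-0.75 ± 0.31), IL9 (0.32 ± 0.82), CSF2 (0.07 ± 0.25), AREG (0.5 ± 0.71), GATA3 (0.14 ± 0.24) and IL1RL1 (-0.7 ± 0.24) were not called either, with paired adjusted p-values from 0.17 for IL1RL1 to 0.92 for CSF2. PPARG (ENSG00000132170.24, chromosome 3, 12287368 to 12434356) stood at 249 ± 55.9 and 215 ± 40.9 CPM (-0.2 ± 0.2, adjusted p = 0.669). Of the 23 tested PPAR targets (median -0.22), 1 was called in the paired fit: PLIN2, the lipid droplet gene, rose from 494 ± 33.7 to 811 ± 137 CPM (adjusted p = 0.0313, and 0.381 unpaired). PLIN2 lost its call whichever 1 of the 6 libraries was left out. CD36 (-1.0 ± 0.41), FABP5 (-0.29 ± 0.23) and CPT1A (-0.43 ± 0.21) were not called, with adjusted p-values from 0.253 to 0.563.

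Over all genes, the unpaired fit called 21 genes higher and 0 lower, with 851 at an unadjusted p under 0.05, while DESeq2 called 124 higher and 4 lower and limma voom 28 in all. The paired fit called 250 higher and 82 lower, and all 21 genes of the unpaired fit were among them. With total counts in place of TMM the median log2 change of all genes moved from -0.10 to -0.19, and the paired fit called 214 higher and 190 lower. The unpaired count of 21 was 0, 0 and 1 without the IL-33 library of replicate 1, 2 or 3, 3, 1 and 2 without the PKS3053 plus IL-33 library of those numbers, and 0 with all libraries of any 1 replicate number left out. Among the named genes, 0, 0 and 1 of the 15 named called genes stayed called without the IL-33 library of replicate 1, 2 or 3. Without the PKS3053 plus IL-33 library of replicate 1, 2 or 3, 3, 1 and 2 stayed called. The paired count of 332 was 171, 116 and 316 without the IL-33 library of replicate 1, 2 or 3. It was 341, 125 (116 higher and 9 lower) and 223 without the PKS3053 plus IL-33 library of replicate 1, 2 or 3, and 514, 40 and 289 without all libraries of replicate 1, 2 or 3. Of the 57 named genes called in the paired fit, 36, 30 and 45 stayed called without the IL-33 library of replicate 1, 2 or 3, and 45, 28 and 42 without the PKS3053 plus IL-33 library of those numbers.

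**Figure D2:**
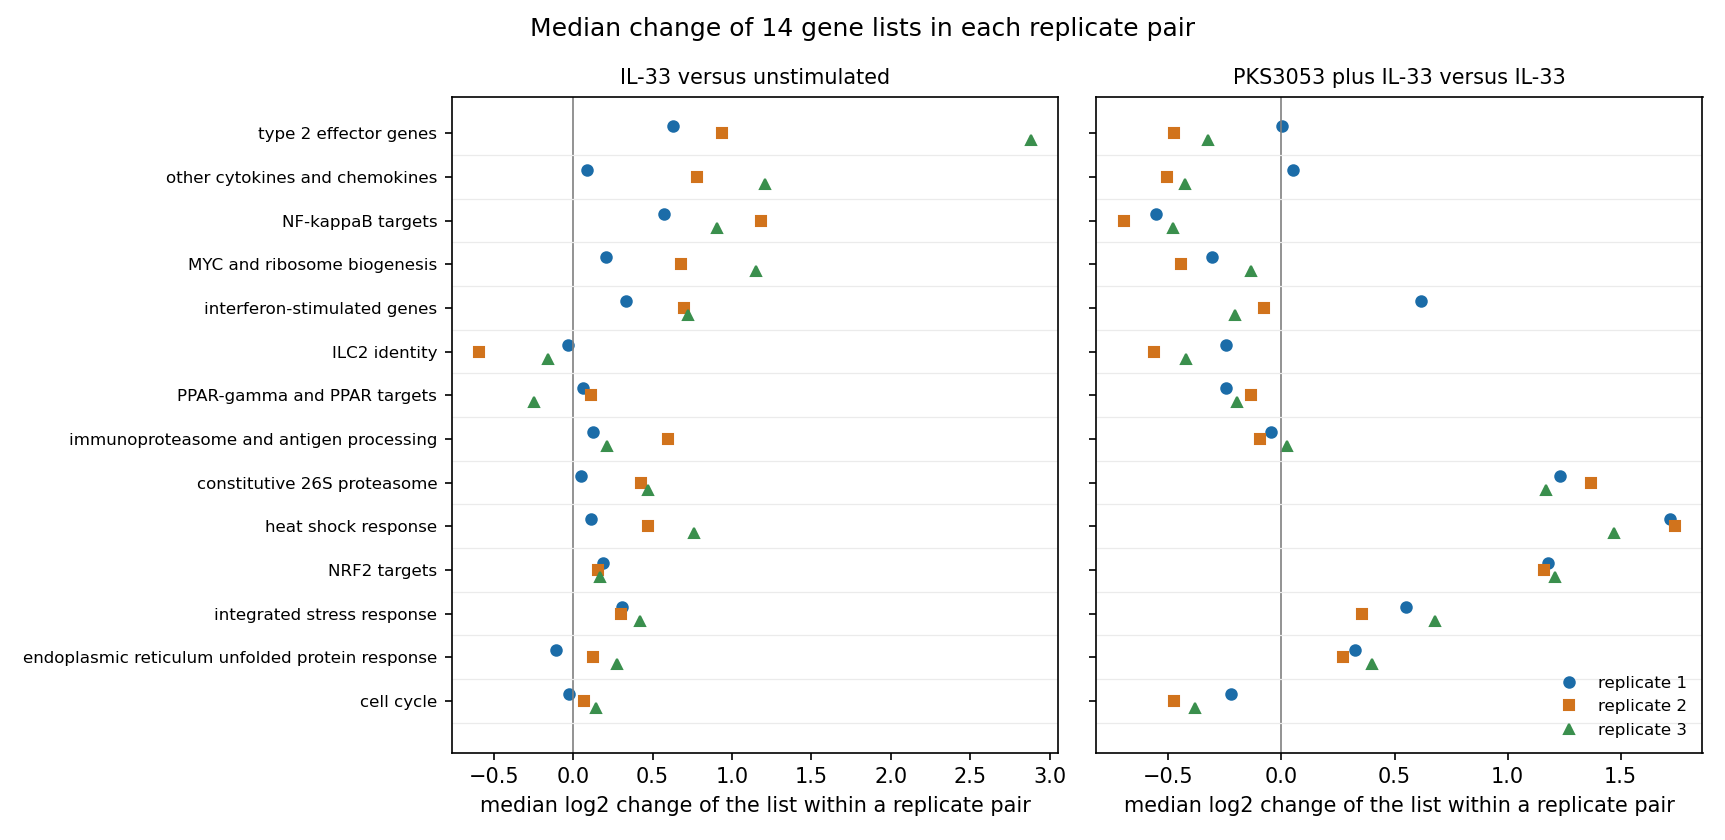
Median log2 change of 14 gene lists in each replicate pair, for IL-33 minus unstimulated and for PKS3053 plus IL-33 minus IL-33, with 1 point per pair. In the second panel the heat shock list lies at 1.72, 1.74 and 1.47 and the NF-κB targets at -0.56, -0.70 and -0.48 in pairs 1, 2 and 3.

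To see both treatments against resting cells, PKS3053 plus IL-33 was compared with the unstimulated group. The proteasome, heat shock and NRF2 lists were above their resting levels, and IL5 and IL13 were called above them in the paired fit. OSGIN1 rose from 1.11 ± 0.378 to 96.8 ± 52.0 CPM (n = 3), a log2 change of 6.44 ± 0.6 in the unpaired fit with an adjusted p = 0.00842. PSMB2 rose from 212 ± 6.7 to 760 ± 22.5 CPM, a log2 change of 1.84 ± 0.17 (adjusted p = 0.00842), and HSP90AB1 from 1191 ± 249 to 6993 ± 613 CPM, a log2 change of 2.55 ± 0.3 (adjusted p = 0.0147). IL5 rose from 502 ± 178 to 3176 ± 1814 CPM, called in the paired fit (2.44 ± 0.42, adjusted p = 0.00452) and not in the unpaired one (adjusted p = 0.0936). HPGD (ENSG00000164120.14, chromosome 4, 174490177 to 174523154), which encodes an enzyme that breaks down prostaglandins, fell from 275 ± 100 to 75.9 ± 19.5 CPM, a log2 change of -1.85 ± 0.31 in the unpaired fit (adjusted p = 0.0445).

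Among the largest rises of the unpaired fit were OSGIN1, BAG3 (23.6-fold), UCHL1 (17.1-fold), FAM241B (8.69-fold), DNAJB1 (8.42-fold), MLLT11 (8.32-fold) and BRF2 (8.19-fold). Smaller rises were those of ZFAND2A (7.1-fold) and DNAJA4 (6.63-fold). The genes that fell without overlap were HPGD, ZNF652 (-1.6 ± 0.27), C3AR1 (-1.37 ± 0.2) and SFXN3 (-1.17 ± 0.2). In the paired fit IL22 rose 10.5-fold, B4GALNT1 9.4-fold, FOSL1 9.38-fold and HSPA6 8.28-fold. The largest falls of that fit were PEAK3 (-2.7 ± 0.42), NMUR1 (ENSG00000171596.7, chromosome 2, 231523160 to 231530495), the receptor gene for neuromedin U (-2.56 ± 0.34), PRAM1 (-2.49 ± 0.42), ZC3HAV1L (-2.26 ± 0.39) and HDAC5 (-2.1 ± 0.41). CCR2 (-2.05 ± 0.31), SEMA4C (-1.99 ± 0.34), B3GNT8 (-1.99 ± 0.36), RAP1GAP2 (-1.98 ± 0.44) and NAA80 (-1.96 ± 0.34) followed. Unpaired adjusted p-values of these 10 genes ran from 0.0784 for NAA80 to 0.44 for RAP1GAP2. RAP1GAP2 lost its paired call without the shallow library, without the PKS3053 plus IL-33 library of replicate 1 or without the unstimulated library of replicate 3, and HDAC5 without the last of these.

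Constitutive 26S proteasome genes had a median log2 change of 1.59 (camera adjusted p = 1.12e-46, and adjusted p = 0.0245 with an estimated correlation), with 20 of 34 members called in the unpaired and 32 in the paired fit, and 32 and 33 adjusted over the list alone. PSMD11 (4.08-fold), VCP (3.51-fold) and PSMB7 (3.77-fold) were among those called in both fits. Heat shock genes had a median of 2.17 (adjusted p = 2.61e-35, and adjusted p = 0.00874 with an estimated correlation), with 13 of 22 called in the unpaired fit, HSP90AA1 and CHORDC1 among them, and 21 in the paired fit. NRF2 targets had a median of 1.40 (adjusted p = 1.78e-15, and adjusted p = 0.00327 with an estimated correlation), with 5 of 20 called in the unpaired fit, PIR, TALDO1 and FTL among them, and 14 in the paired fit. Integrated stress response genes had a median of 1.01 (adjusted p = 7.7e-10, and adjusted p = 0.0218 with an estimated correlation), with 0 of 23 called in the unpaired and 12 in the paired fit. Among these, ATF3 rose 4.36-fold, SLC3A2 3.01-fold, SLC7A11 6.14-fold and PPP1R15A 2.44-fold. Without the shallow library 32 proteasome, 21 heat shock, 13 NRF2 and 10 integrated stress response genes stayed called in the paired fit. The estimated correlation gave 0 called lists in the paired fit, with an adjusted p = 0.154 for the proteasome, 0.131 for heat shock, 0.122 for NRF2 targets and 0.154 for the integrated stress response.

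NF-κB targets were above the unstimulated level as a set, with a median log2 change of 0.43 (adjusted p = 0.00515, and adjusted p = 0.194 with an estimated correlation), and NFKBIZ (2.07 ± 0.29), NFKBIA (0.8 ± 0.18), CD40LG (0.72 ± 0.16) and SOD2 (0.66 ± 0.17) rose in the paired fit. Of these 4, NFKBIZ alone stayed called without the shallow library, and SOD2 lost its call with total counts too. Interferon-stimulated genes had a median of 0.65 (adjusted p = 0.000578, and adjusted p = 0.778 with an estimated correlation), and 10 of 24 rose in the paired fit, among them MX1 (2.91-fold), IFIT3 (4.0-fold), IFIT1 (3.86-fold) and RSAD2 (2.44-fold). Of the ILC2 identity genes 1 fell in the unpaired fit, HPGD, and 4 rose and 6 fell in the paired fit. IL17RB rose 1.95-fold, ICOS 2.28-fold, TNFRSF25 1.84-fold and IL1RL1 2.2-fold, and KLRG1 fell 2.88-fold. The type 2 effector list rose (0.69, adjusted p = 0.0150, and adjusted p = 0.579 with an estimated correlation) although TNFSF11 fell (-1.44 ± 0.23), and CXCL8 (2.0 ± 0.31) and CXCL10 (2.02 ± 0.46) rose, all in the paired fit. TNFRSF25 and CXCL10 lost their calls without the shallow library, and IL1RL1 without the unstimulated or the PKS3053 plus IL-33 library of replicate 3. With total counts TNFRSF25 lost its call as well.

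Camera called 8 further lists upward in the unpaired fit, none of them with an estimated correlation. They were the unfolded protein response (median 0.39, adjusted p = 7.8e-05, and adjusted p = 0.141 with an estimated correlation), oxidative phosphorylation (0.34, adjusted p = 3.87e-05), ribosomal proteins (0.24, adjusted p = 0.00129) and MYC with ribosome biogenesis (0.54, adjusted p = 0.00328). Glycolysis (0.21, adjusted p = 0.0182), the immunoproteasome list (0.24, adjusted p = 0.0182), other cytokines (0.41, adjusted p = 0.0324) and cholesterol biosynthesis (0.26, adjusted p = 0.0343) completed them. Not all were higher in each pair. In the pairs of replicates 1, 2 and 3, MYC with ribosome biogenesis had medians of -0.0757, 0.343 and 1.02. Ribosomal proteins had 0.513, 0.317 and -0.0156, and cholesterol biosynthesis -0.0171, 0.277 and 0.522. The remaining lists named here had positive medians in each pair. With an estimated correlation the adjusted p = 0.693 for oxidative phosphorylation, glycolysis and other cytokines, 0.789 for ribosomal proteins, 0.778 for MYC and cholesterol, and 0.438 for the immunoproteasome list. HSPA5 rose 2.33-fold and NDUFA4 1.88-fold in the paired fit. The block added 3 lists, all lower. Cell cycle genes had a paired median of -0.34 (adjusted p = 0.0104, against 0.119 unpaired) with 2 members called, TOP2A and BIRC5. T cell markers had a median of -0.57 (adjusted p = 0.00153, against 0.278 unpaired) with 5 of 15 called, among them LCK (1026 ± 366 to 563 ± 276 CPM), TRAC, CD4 and TRDC. In the unstimulated library of replicate 2, LCK, TRDC and TRAC stood at 786, 384 and 164 CPM of the library total, where CD3G and CD8A stood at 0.347. Falls of LCK, TRDC and TRAC therefore do not by themselves show fewer T cells. Monocyte markers had a median of -0.82 (adjusted p = 0.0103, against 0.0501 unpaired) with 3 of 11 called, CSF1R, CD14 and LYZ, of which CSF1R and CD14 averaged 1.5 ± 0.876 and 1.62 ± 0.98 CPM unstimulated, under the limit of a count of 0 in the shallow library, and lost their calls with DESeq2. With an estimated correlation these 3 lists had an adjusted p = 0.401, 0.401 and 0.408. Without the shallow library 0 cell cycle, 1 T cell (LCK) and 0 monocyte members were called in the paired fit. The other 13 lists had unpaired camera adjusted p-values of at least 0.278, that of ILC2 identity.

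IL13 (2.16 ± 0.48), CSF2 (2.21 ± 0.26), PSMB5 (1.8 ± 0.19) and PLIN2 (0.84 ± 0.15) rose in the paired fit, and the PPAR targets ABCG1 (-1.98 ± 0.29) and CAT (-0.78 ± 0.17) fell. IL13 and CAT lost their calls without the shallow library. The unpaired adjusted p-values of these 6 genes ran from 0.0734 for PSMB5 to 0.587 for ABCG1, and the PPAR list had a median of -0.29 with a camera adjusted p = 0.712. IL4 (0.44 ± 0.32), IL9 (1.61 ± 0.96), AREG (0.57 ± 0.7), GATA3 (0.34 ± 0.24), PPARG (0.56 ± 0.2), CD36 (-0.52 ± 0.39), FABP5 (0.34 ± 0.23) and CPT1A (-0.65 ± 0.21) were not called. Neither were PSMB8 (0.17 ± 0.15), PSMB9 (0.15 ± 0.15) and PSMB10 (0.41 ± 0.17), and the paired adjusted p-values of these 11 genes ran from 0.0689 for CPT1A to 0.654 for AREG.

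Over all genes the unpaired fit called 82 higher and 5 lower, with 1599 at an unadjusted p under 0.05, and DESeq2 called 254 higher and 127 lower. The paired fit called 751 higher and 700 lower, the 87 genes of the unpaired fit among them. With total counts the median log2 change of all genes moved from -0.09 to -0.27 in the paired fit, and 490 genes were called higher and 1553 lower. The unpaired count of 87 was 61, 1 and 2 without the unstimulated library of replicate 1, 2 or 3, 29, 5 and 5 without the PKS3053 plus IL-33 library of those numbers, and 0 with all libraries of any 1 replicate number left out. Of the 23 named genes called there, 17, 1 and 2 stayed called without the unstimulated library of replicate 1, 2 or 3, and 11, 5 and 4 without the PKS3053 plus IL-33 library of those numbers. The paired count of 1451 was 766 and 696 without the unstimulated library of replicate 2 or 3, 666 and 828 without the PKS3053 plus IL-33 library of replicate 2 or 3, and 253 and 731 without all libraries of replicate 2 or 3. Of the 75 named genes called in the paired fit, 70, 63 and 60 stayed called without the unstimulated library of replicate 1, 2 or 3, and 72, 59 and 62 without the PKS3053 plus IL-33 library of those numbers.

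To ask whether PKS3053 acted on the genes that IL-33 moved, both responses were set side by side. Of the 79 genes that IL-33 raised in the paired fit, 5 were called lower when PKS3053 was added. They were the NF-κB family gene REL, the chemokine receptor gene CCR4, the phosphatase gene DUSP2, the TNF family gene CD70 (1.33 ± 0.2 with IL-33 and -0.87 ± 0.2 with PKS3053 added) and ODAPH (1.96 and -1.18). IL7R, which IL-33 lowered, was called higher with PKS3053. HSP90AB1 (0.99 and 1.58) and SLC3A2 (0.83 and 0.76) were raised in both steps. None of REL, CCR4, DUSP2, CD70 and ODAPH was called lower with PKS3053 without the shallow library, and IL7R and SLC3A2 were not called higher. The IL-33 calls of REL, CCR4, DUSP2, CD70 and ODAPH, and those of IL7R, HSP90AB1 and SLC3A2, were each lost without the IL-33 library of replicate 2. Those of HSP90AB1 and SLC3A2 were also lost with DESeq2 size factors or with total counts, and that of IL7R with the size factors. The IL-33 libraries enter both comparisons with opposite sign, which by itself favours opposite calls, and the number expected from that was not estimated. With PKS3053 plus IL-33, 55 of the 79 genes were called above the unstimulated level.

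Across the 15045 genes, which are not independent replicates, the log2 changes of the IL-33 and PKS3053 comparisons had a correlation of -0.135 and a covariance of -0.04 in the unpaired fit. Counts simulated without any effect gave a mean correlation of -0.452 (from -0.469 to -0.437 in 20 simulations) and a covariance of -0.0866, because the IL-33 libraries enter both with opposite sign. The observed covariance was 0.0466 above the simulated one, and 0.0366 above it in the paired fit, where the correlation was -0.142 and the simulated one -0.463. Over the 9629 genes with a mean of at least 5 CPM the correlation was -0.0102, against -0.471 in simulations.

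Some markers of other cell types differed more between replicate numbers than between groups. In CPM of the library total, the T cell gene CD8A stood at 107, 80.3 and 79.6 in the unstimulated, IL-33 and PKS3053 plus IL-33 libraries of replicate 3 and at 1.91 or less in the other 6 libraries. The NK cell gene GNLY stood at 1490, 1100 and 1090 in replicate 3 and at 202 or less elsewhere. The platelet gene PPBP stood at 820, 758 and 578 in replicate 1 and at 2.93 or less elsewhere. CLC, a granule gene of eosinophils and basophils, ranged from 50.6 to 567 over the 9 libraries. These 4 genes were chosen after their values were seen.

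**Figure D3:**
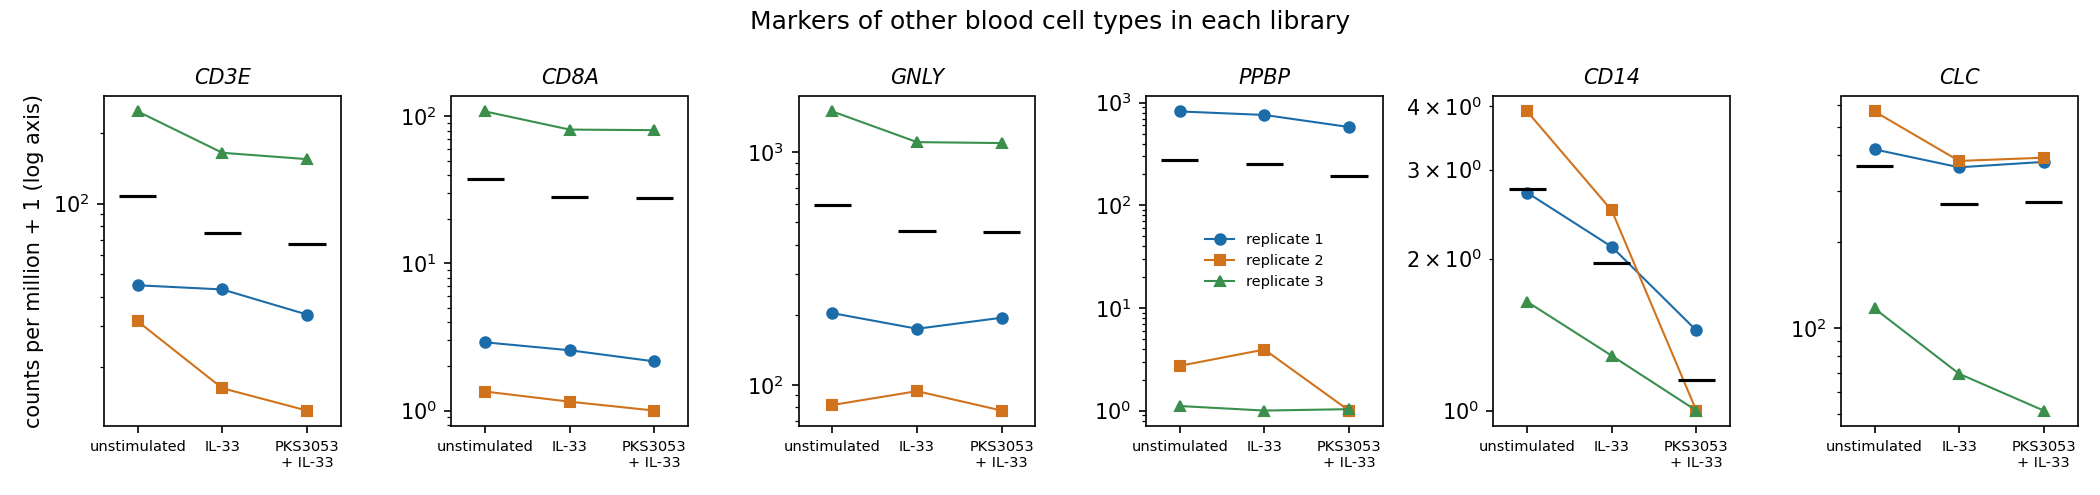
CPM of the library total plus 1 of CD3E, CD8A, GNLY, PPBP, CD14 and CLC in the 9 libraries on a log axis, grouped by treatment, with 1 symbol per replicate number. CD8A reaches 107 CPM in replicate 3 and PPBP 820 CPM in replicate 1, while CD14 stays at 2.91 CPM or less.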

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

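The replicate block, the DESeq2, limma voom, scaling, filter, fold and leave-out settings of the unpaired fit were set before the data were examined, while the thinning to the shallowest library and all settings of the paired fit other than the block itself were chosen after the results were seen. The named genes were followed under the block, DESeq2, size factor, total count and single-library settings only, and none of these reversed the direction of a called one.

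The block mattered most for the numbers of genes called. With it the IL-33 comparison went from 0 to 87 genes, the PKS3053 comparison from 21 to 332 and PKS3053 plus IL-33 against unstimulated from 87 to 1451; without it the paired counts return to 0, 21 and 87. DESeq2 in the unpaired design called 17, 128 and 381 genes. Total counts without TMM gave 12 genes for the PKS3053 comparison, thinning to the shallowest library 40, and a fit of the compared groups alone 2, as it did for PKS3053 plus IL-33 against unstimulated. Leaving out a library or a replicate number gave 0 to 3 genes for the PKS3053 comparison and 0 to 61 against unstimulated. The remaining unpaired settings kept the PKS3053 count between 21 and 29 and the count against unstimulated between 73 and 111. Fewer libraries leave fewer degrees of freedom, which is part of the construction of the leave-out settings. For the other changes the cause was not tested.

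In the paired fit the IL-33 count of 87 was 351 with DESeq2, 132 with limma voom, 52 with size factors, 51 with total counts, 476 without a filter and 50 with a filter at 1 CPM, and 0 to 896 when a library or replicate number was left out. The PKS3053 count of 332 was 756 with DESeq2, 862 (391 higher and 471 lower) without a filter, 217 with at least a 2-fold change and 40 to 514 in the leave-out settings. The count of 1451 against unstimulated was 782 with at least a 2-fold change and 253 to 1971 in the leave-out settings. Thinning all libraries to the depth of the shallowest gave 98, 323 and 1100 genes. The cause was not tested, except that a minimum fold can only remove genes.

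Camera with a preset correlation called 13, 9 and 15 lists in the unpaired fit and 15, 9 and 18 with the block. With an estimated correlation it called 1, 4 and 4 in the unpaired fit and 0, 0 and 0 in the paired fit. Fry called 1, 4 and 5 in the unpaired fit and 0 and 5 for the IL-33 and PKS3053 comparisons in the paired fit, against 12 for PKS3053 plus IL-33 against unstimulated. Leaving out a replicate number gave 10 to 13, 7 to 9 and 10 to 16 lists in the unpaired fit. In the paired fit the leave-out settings gave 13 to 14, 10 to 12 and 13 to 17. For the comparisons with PKS3053, those paired settings also include leaving out the shallow library alone. No list that camera called changed the sign of its median under total counts or DESeq2 size factors. Fry asks another question than camera, so its counts need not match. The correlation across genes between the 2 responses stayed below 0 in every setting. The shared IL-33 libraries give that sign without any effect (a mean of -0.452 in the simulations of the unpaired fit), so the sign carries no support. It was -0.278 (covariance -0.174) with DESeq2 and -0.202 to -0.146 (covariance -0.0921 to -0.0694) without one of the replicate numbers. Over genes with a mean of at least 5 CPM it was -0.0102. The simulations were not repeated for DESeq2 or the leave-out settings.

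The named genes made 214 gene-by-comparison results, of which the unpaired fit called 38 and the paired fit 171. Of the 2140 values they took under other settings than the unpaired fit, 1642 kept direction and side of the threshold, 188 no longer passed it, 184 passed it where they had not, and 126 were uncalled values that moved by more than their SE or changed sign. For the paired fit these numbers were 1635, 446, 11 and 48 of 2140. Depth limits what the shallow library can show: 1 count is 0.75 CPM there and 0.0315 to 0.0693 CPM in the others. Without it the paired fit called 125 genes for PKS3053 against IL-33 and 666 against unstimulated.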

Other observations

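Chosen after the results were seen were the genes of the opening paragraph, the tests of the shallow library and of the shared replicate differences, and the splits for the unpaired IL-33 comparison. The ILC2 libraries held abundant transcripts of granule genes. In CPM of the library total, GZMB ranged from 1150 to 8470 and GZMA from 301 to 2160 over the 9 libraries, and EPX, which encodes eosinophil peroxidase, from 337 to 2190. In replicate 3 GZMB stood at 3930 unstimulated, 8470 with IL-33 and 8430 with PKS3053 plus IL-33, while in replicate 1 it stood at 3250, 2080 and 2300. IL22 reached 248 with IL-33 and 262 with PKS3053 plus IL-33 in replicate 3, against 27.9 and 55.5 in replicate 2, and IL17F was highest in replicate 2, at 9.56, 30.3 and 27.8. KIT ranged from 221 to 708 and was highest in replicate 1 in each group. HBB stood at 68.6, 88.5 and 141 in replicate 1 and at 8.25 or less in the other 6 libraries.

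Proteasome genes were higher with PKS3053 than with IL-33 alone. The shallow library cannot be their whole source, since the list's median log2 change in the pairs of replicates 1 and 3 was at least 1.17. Total counts lower the list's paired median from 1.30 to 1.21. Proteasome activity was not measured, and neither its loss nor other sources of protein stress were tested. Reduced PPARγ activity stays open. The list of PPAR targets had medians of -0.244, -0.133 and -0.196 in the 3 pairs. All genes with a mean of at least 5 CPM had medians of -0.0581, -0.121 and -0.0241 there. The list lay barely below them in pair 2, but its medians were taken without that minimum, so the gene sets are unlike. Of its 23 tested members 10 were lower in all pairs and 2 higher, and the share over all genes is not given here. PLIN2, its only called member in the paired fit, rose. The list's camera adjusted p = 0.749 missed the threshold.

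For IL-33, edgeR called 0 genes without the block and 87 with it. Without the block 347 genes had an unadjusted p under 0.05, where chance gives 752, and DESeq2 called 17 and limma voom 0. A difference shared by libraries of one replicate number is a candidate explanation, since deviations of same-numbered libraries had correlations of at least 0.462. The common dispersion was 0.325 without the block and 0.0481 with it. The 0 calls without the block therefore do not show that IL-33 changed no gene. What the number stands for (a donor, a culture or a batch) is not given in the sources used here, and the count table puts an unexplained letter D before it. No biological explanation was tested.

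Genes raised by IL-33 tended to be lower when PKS3053 was added. Over all genes the relation did not show a reversal. The unpaired covariance of -0.04 was less negative than the -0.0866 simulated without any effect. The IL-33 libraries enter both comparisons, so the 100 genes raised most by IL-33 in a pair of replicates were followed in the replicate left out. Their median change with PKS3053 minus that of all genes was -0.153 (SE 0.116), -0.397 (SE 0.170) and -0.392 (SE 0.110) for replicates 1, 2 and 3, and 57, 70 and 78 of the 100 lay below the median of all genes. The left-out IL-33 library takes no part in the choice of genes, so its error alone would not lower these genes there. All 3 values lie below the bound of -0.1 set before. The highest, -0.153, lies within its SE of that bound, a margin added after the values were seen. The SE treats the genes as independent, and the value of replicate 2 rests on the shallow library. Only the value of replicate 3 lies more than its SE below the bound without resting on the shallow library. The test therefore does not decide whether the shared libraries are the whole source. A weaker cytokine response under PKS3053 stays open.

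With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the unpaired fit the real split gave 0, 21 and 87 genes for IL-33, for PKS3053 and for PKS3053 plus IL-33 against unstimulated, and the highest other split gave 0 in each. With the labels exchanged within replicate numbers there are 4 arrangements, also too few, and the real one gave 87, 332 and 1451 genes where the highest other gave 0.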
